A study of Mus musculus with 15 samples.

How the data were processed

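Gene expression was measured with whole-genome Affymetrix mouse arrays in the heart apex of male mice of 3 kinds, with 5 arrays each. C3H (C3H/HeJ) and C57Bl/6 (C57BL/6J) are inbred strains, and B6C3F1 is the first-generation cross between them. Per the labels' protocols, the mice carried an abdominal radiotelemetry transmitter implanted at 7 weeks of age, received no other treatment and were 9 to 10 weeks old at collection. Total RNA (50 ng) was amplified in a two-cycle labelling reaction, so that transcripts were copied more than once before they reached the array.

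The deposited values are log2 values, and the submitters' processing notes name MAS5, the Affymetrix method that gives 1 signal per probe set. Its version is not given in the sources used here. No header states the log2 step or the scaling. Both were read from the values: on the linear scale the 2% trimmed mean was close to 500.26 on each of the 15 arrays. No detection call per probe set was used here, and no depth exists for such data, so that the number of arrays limits the precision. The table holds 45096 probe sets. Of these, 64 are controls, 34940 have 1 gene symbol, 932 have several and 9160 have none given in the annotation used. Of the probe sets with 1 symbol, 34736 matched a gene identifier of the GRCm38.p6 gene table, and 0 symbols changed. The array values name no genome build, so that gene coordinates are not printed.

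The log2 values were returned to the linear scale, 16 was added and log2 was taken again. All differences below are on that log2(signal + 16) scale, which understates the change of low genes. A gene was represented by its probe set of highest mean, and sets below the 40th percentile of all means (5.74) were left out. This left 13111 of 18190 genes, of which 1452 rest on a probe set whose design can match several transcripts. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 15 arrays in one fit and Benjamini-Hochberg adjustment over the genes. A gene passed at an adjusted p under 0.05. The 4 contrasts were C3H minus C57Bl/6, B6C3F1 minus C57Bl/6, B6C3F1 minus C3H, and B6C3F1 minus the midparent (the mean of both parental log2 means). Adjusted p-values for single genes are from this limma fit throughout. The position of each B6C3F1 array was its least-squares place on the line from the C57Bl/6 mean (0) to the C3H mean (1) over the genes that passed between the parents.

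There were 29 gene lists, written from general knowledge of the heart before the data were examined, as were the contrasts and the rule for naming genes. Tests and alternatives chosen after the data were seen are named as such where they are given. Each list was tested with limma's camera at an inter-gene correlation of 0.01, with an estimated correlation beside it and with fry, which tests the members without setting them against other genes. The rule names the 10 genes with the largest rise and the 10 with the largest fall between the parents among those whose arrays do not overlap, 5 each way in the B6C3F1 contrasts, up to 4 members of each list described, and always Nnt, H2-Ea, Myh6, Myh7, Nppa and Nppb. Which lists to describe was decided after their results were seen. Other members are named from their list where they passed, and were chosen after their values were seen.

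The procedure was tested on simulated data in which 200 of 13111 genes were changed. For C3H minus C57Bl/6, 59.7% of the genes changed 1.5-fold, 74.6% of those changed 2-fold and 92.4% of those changed 4-fold were found, and 9 unchanged genes were called. For B6C3F1 minus C57Bl/6 the shares were 58.2%, 80.6% and 97.0%. For B6C3F1 minus C3H they were 50.7%, 71.6% and 95.5%. For B6C3F1 minus midparent they were 55.2%, 74.6% and 98.5%. In the C3H minus C57Bl/6 simulation of lists, a list shifted by 0.4 was called in 17 of 20 draws when 2000 other genes differed, and 4 of 560 unshifted lists were called. The simulated genes varied independently and their lists were random. These rates thus do not cover lists of correlated members, such as antigen presentation (estimated correlation 0.28).

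Alternatives covered the pseudocount (1 and 64), the dim filter (none, or the 60th percentile), quantile normalization, centring each array on its median, every probe set, leaving out probe sets ending in _x_at or _s_at, eBayes without a trend or robust, only the 2 strains compared, the replicate number as a block, the Gapdh 3 prime over 5 prime ratio as a covariate, array weights, a 1.5-fold minimum and leaving out each array. Probe sets with several symbols or none given were left out of the tests. Each array is labelled as a separate mouse. Sample numbers in the labels run in 1 block per strain, so that an effect of handling order and an effect of strain cannot be told apart. The labels give no hybridisation batch.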

Results

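The hearts of 3 kinds of male mice were compared without any treatment: the inbred strains C3H and C57Bl/6 and their first-generation cross B6C3F1. The study set cardiac gene expression beside the heart physiology and pathology of these mice. Each group had 5 arrays of apex RNA. The 2% trimmed mean signal was close to 500.26 on each array, and no 2 arrays held identical values. The first principal component held 23.4% of the variance and placed all C3H arrays at one end (25.3 to 35.4), all C57Bl/6 arrays at the other (-29.1 to -23.6) and all B6C3F1 arrays between them (-5.91 to 1.29). Poly-A control RNAs added during labelling were brighter on the C3H arrays (mean log2 11.05 ± 0.80, SD, n = 5) than on the C57Bl/6 (10.26 ± 0.57) and B6C3F1 arrays (10.33 ± 0.13). The exact two-sided permutation p was 0.00794 for C3H against each of the others, the smallest that 5 against 5 arrays can give, and 0.0714 after Benjamini-Hochberg adjustment over 18 such tests. The Gapdh 3 prime over 5 prime ratio, a sign of RNA integrity, was 0.60 ± 0.26 in C3H, 0.90 ± 0.21 in B6C3F1 and 0.85 ± 0.24 in C57Bl/6 on the log2 scale.

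The first question was how the hearts of the inbred strains differ. Myh7, the slow beta myosin heavy chain that predominates in the fetal mouse ventricle, was 5.51-fold higher in C3H than in C57Bl/6 hearts (log2 difference 2.46 ± 0.17, SE, adjusted p = 2.46e-09). Its signal was 11.66 ± 0.40 (SD, n = 5) in C3H and 9.20 ± 0.20 in C57Bl/6. Myh6, the adult alpha chain, differed by -0.26 ± 0.12 (adjusted p = 0.167), and a second, dimmer probe set of Myh6 was higher in C3H by 0.93 (adjusted p = 0.00336 over all probe sets). The natriuretic peptide genes did not pass: Nppa differed by 0.82 (adjusted p = 0.0703) and Nppb by -0.64 (adjusted p = 0.354). Nppa did pass without C3H replicate 3 (adjusted p = 0.0234), B6C3F1 replicate 2 (0.0396) or B6C3F1 replicate 5 (0.041), and after centring each array on its median (0.0345). Of 13111 genes tested, 2052 passed, 951 higher and 1101 lower in C3H, and 1363 passed with the poly-A control signal as a covariate, an alternative added after the data were seen. The median standard error of a log2 difference was 0.16. Among the passing genes, 225 were at least 2-fold higher and 273 at least 2-fold lower. Centring each array on its median moved the balance to 1277 higher and 620 lower. That step moved the median of all genes from -0.02 to 0.08, so that small differences of direction depend on the scaling.

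Of the 17 tested members of the list for the fetal and stress programme of the ventricle, 7 were higher in C3H and 1 was lower. Beside Myh7, the higher members included Myl4, an atrial and embryonic myosin light chain (2.23-fold), Fhl1, a sarcomere-associated stress sensor (1.66-fold), and Hk1, a hexokinase (1.45-fold), and the others were Timp1, Ccn2 and Xirp1. The lower member was Cilp (-0.99). Adjusted over the list alone, 9 were higher and 1 was lower. The list passed camera at an adjusted p of 0.000596, against an adjusted p = 0.119 with an estimated correlation. With the poly-A control signal as a covariate Hk1 did not pass (adjusted p = 0.0682). The fry adjusted p of the list was 0.000109. Myl4 is also an atrial marker: of 11 such genes it alone was higher and Kcna5 alone lower (2 and 1 adjusted over the list alone), with an adjusted p of 0.281 by camera, 0.00271 by fry and 0.586 with an estimated correlation. Of 35 tested extracellular matrix and fibrosis genes, 8 were higher in C3H and 0 lower, also when adjusted over the list alone. They included Thbs4, a matrix protein of stressed muscle (3.64-fold), Timp3, an inhibitor of matrix proteases (2.29-fold), Tcf21, a transcription factor of cardiac fibroblasts (1.69-fold), and Dcn, which codes for decorin (1.33-fold). Dcn did not pass with the poly-A control signal as a covariate (adjusted p = 0.0654). The list's adjusted p was 0.0378 with camera, 0.128 with fry, and adjusted p = 0.618 with an estimated correlation. Most members did not pass, and the list's median difference was 0.08. The list did not pass after quantile normalization (adjusted p = 0.0572), after centring each array on its median (0.0556) or with the Gapdh ratio as a covariate (0.281). It did not pass either without any one of C3H replicates 2 and 5 and C57Bl/6 replicates 1 and 4 (0.0621 to 0.202).

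**Figure D1:**
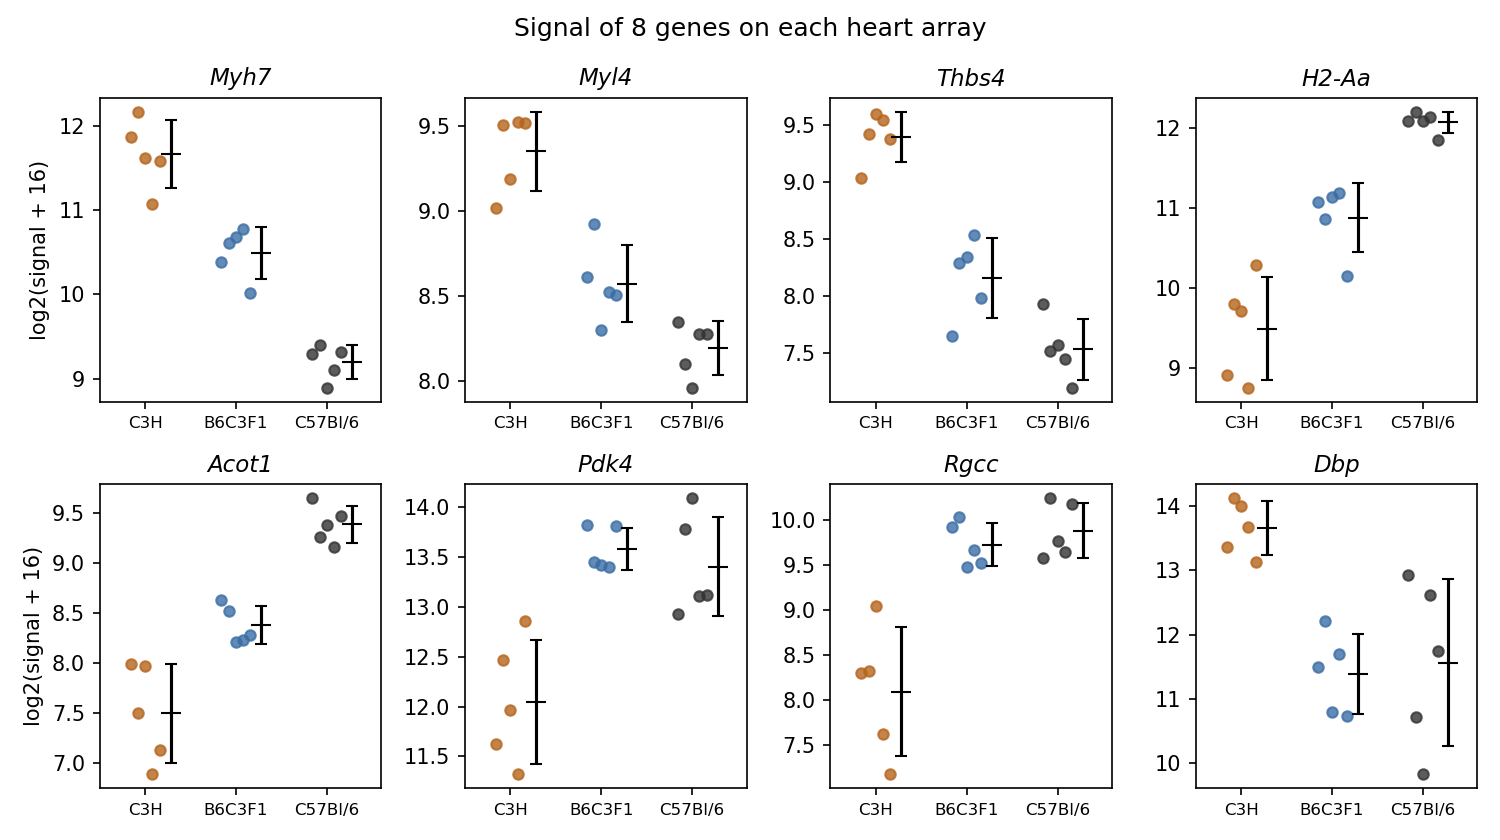
The log2(signal + 16) of 8 genes is shown for each of the 15 arrays, with the mean and SD of the 5 arrays of a strain beside the points. For Myh7, Myl4, Thbs4, H2-Aa and Acot1 the B6C3F1 arrays lay between the parental means, while for Pdk4, Rgcc and Dbp they lay near the level of C57Bl/6.

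Antigen presentation had the smallest camera p between the parents at the preset correlation, while fry gave the list of inherited differences a smaller one (adjusted p = 2.33e-06 against 1.6e-05). Of 16 tested members, 10 were lower in C3H and 0 higher, adjusted over all genes and over the list alone. The class II genes H2-Aa and H2-Eb1, whose products present peptides to T cells, were 5.98-fold and 4.21-fold lower. Probe sequence may contribute to both of these differences and was not tested for them singly. Signals of the class I genes H2-K1 and H2-D1 were 34.6-fold and 22.2-fold lower. These 2 genes differ in sequence between strains and belong to a family of close copies. The 3 other probe sets of H2-K1 differed by -3.77, -1.12 and -0.26 (the last at an adjusted p of 0.608 over all probe sets). All of its probe sets can match several transcripts, so that the size of its difference depends on the one chosen. Of the 6 other probe sets of H2-D1, 3 were lower and 3 were higher in C3H, so that its direction depends on the probe set. With probe sets that can match several transcripts left out, H2-D1 differed by -2.07 on the log2 scale. The list's adjusted p was 1.58e-08, and adjusted p = 0.119 with an estimated correlation. Of 29 interferon response genes, 8 were lower and 2 higher in C3H (9 and 2 adjusted over the list alone). The lower ones included the chemokine gene Cxcl9 (6.66-fold, with the C3H level below the dim filter and a log2 difference of -3.93 to -1.65 over the alternatives), Trim30a (2.47-fold), the antiviral gene Rsad2 (2.45-fold) and Gbp3 (1.92-fold). The higher members were Gbp6 (1.04 on the log2 scale) and Ifi35 (0.57). The list's adjusted p was 0.021 with camera, 0.0655 with fry, and adjusted p = 0.6 with an estimated correlation. It did not pass with the poly-A control signal as a covariate (0.0954), at the 60th percentile of the dim filter (0.0585) or without any one of C3H replicate 1 and C57Bl/6 replicates 3 and 5 (0.0699 to 0.0833).

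Genes of fatty acid oxidation were lower in C3H in 11 of 30 cases and higher in 1 (15 and 1 adjusted over the list alone). The acyl-CoA thioesterases Acot1 and Acot2 were 3.71-fold and 1.52-fold lower. Pdk4, the kinase that limits pyruvate oxidation, was 2.57-fold lower, and the auxiliary enzyme gene Decr1 was 1.42-fold lower. The higher member was Slc27a1, a fatty acid transporter (0.60 on the log2 scale). The list's adjusted p was 0.000596, 0.00129 with fry, and adjusted p = 0.398 with an estimated correlation. Of 20 endothelial markers, 5 were lower in C3H and 0 higher, among them Rgcc (3.45-fold), the apelin receptor gene Aplnr (3.24-fold), the tight junction gene Cldn5 (1.57-fold), Esam (1.36-fold) and Cdh5 (-0.56 on the log2 scale). Adjusted over the list alone, 8 were lower and 2 higher. Esam did not pass after centring (adjusted p = 0.133) or with the poly-A control signal as a covariate (0.172). For the endothelial list the adjusted p was 0.0431, 0.00455 with fry, and adjusted p = 0.398 with an estimated correlation. It did not pass after centring each array on its median (0.0556), with the poly-A control signal as a covariate (0.148) or without any one of B6C3F1 replicate 1, C3H replicates 2 and 4 and C57Bl/6 replicates 3 and 5 (0.0537 to 0.0833). Of 25 heat shock and folding genes, 5 were lower and 0 higher (8 and 0 over the list alone), including the mitochondrial chaperonin gene Hspd1 (1.54-fold), Ahsa1 (1.39-fold), Hspa8 (1.33-fold), Fkbp4 (-0.58 on the log2 scale) and Hspa5 (-0.25). The heat shock list's adjusted p was 0.00656 with camera, 0.0623 with fry, and adjusted p = 0.596 with an estimated correlation. It did not pass without C57Bl/6 replicate 2 (0.0983), Ahsa1 did not pass after centring (0.0786), and Hspa8 did not pass when probe sets that can match several transcripts were left out (-0.17, adjusted p = 0.543). The C3H arrays, on which these lists were lower, are also those with the brighter poly-A controls (11.05 against 10.26).

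Members of 4 further lists passed singly, while the lists did not. Among 28 ion channel and conduction genes, 7 were higher and 4 lower in C3H (9 and 4 adjusted over the list alone; camera adjusted p = 0.0538, fry 0.0497, and adjusted p = 0.398 with an estimated correlation). By camera at the preset correlation the list passed in 13 of 30 alternatives. These were the pseudocount of 1, both other dim filters, no probe sets that can match several transcripts, only the 2 strains, the Gapdh covariate, array weights, and leaving out any one of B6C3F1 replicates 3, 4 and 5, C3H replicate 5 and C57Bl/6 replicates 1 and 4 (0.0302 to 0.0476). The KATP channel genes went in opposite directions, with Abcc9 1.69-fold higher and Kcnj11 1.92-fold lower. The T-type calcium channel gene Cacna1h was 4.93-fold lower, to below the dim filter (-3.79 to -1.22 on the log2 scale over the alternatives), and the transcription factor gene Irx3 was 1.86-fold higher. The other lower members were Kcna5 (-0.93) and Kcnj3 (-0.87). Among 20 calcium handling genes, 5 were higher and 2 lower, adjusted over all genes and over the list alone (camera adjusted p = 0.23). Slc8a1, the sodium-calcium exchanger, was 2.31-fold higher by its brightest probe set, but another of its probe sets was lower in C3H by 1.07 on the log2 scale. Itpr2 was 1.72-fold and Asph 1.54-fold higher, and Calr, calreticulin, was 1.54-fold lower. Orai1 (0.43) and Stim1 (0.59) were also higher, and Casq2 was lower (-0.48). Itpr2 did not pass with the poly-A control signal as a covariate (adjusted p = 0.0582) or without probe sets that can match several transcripts (0.0775). Among 43 cardiomyopathy disease genes, 5 were higher and 2 lower (also over the list alone; camera adjusted p = 0.799). Prkag2, a subunit of the AMP-activated kinase, was 2.73-fold lower in C3H, and Jup was lower by -0.40. The higher ones were Myh7, Abcc9, Fhl1, Pkp2 (0.37) and Lmna (0.25), of which Myh7, Abcc9 and Fhl1 also belong to other lists. The median of this list was -0.03 and its mean 0.03. Of 21 circadian clock genes, 6 were higher and 2 lower (also over the list alone; camera adjusted p = 0.0686, and adjusted p = 0.596 with an estimated correlation). Dbp was 4.27-fold, Tspan4 2.19-fold, Wee1 1.83-fold and Hlf 1.57-fold higher in C3H, while Arntl (-0.98) and Clock (-0.45) were lower. Hlf did not pass with the poly-A control signal as a covariate (adjusted p = 0.0899). The clock list passed without any one of C3H replicate 5 and C57Bl/6 replicates 1 and 4 (0.0232 to 0.0348), and with no dim filter (0.0315).

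**Figure D2:**
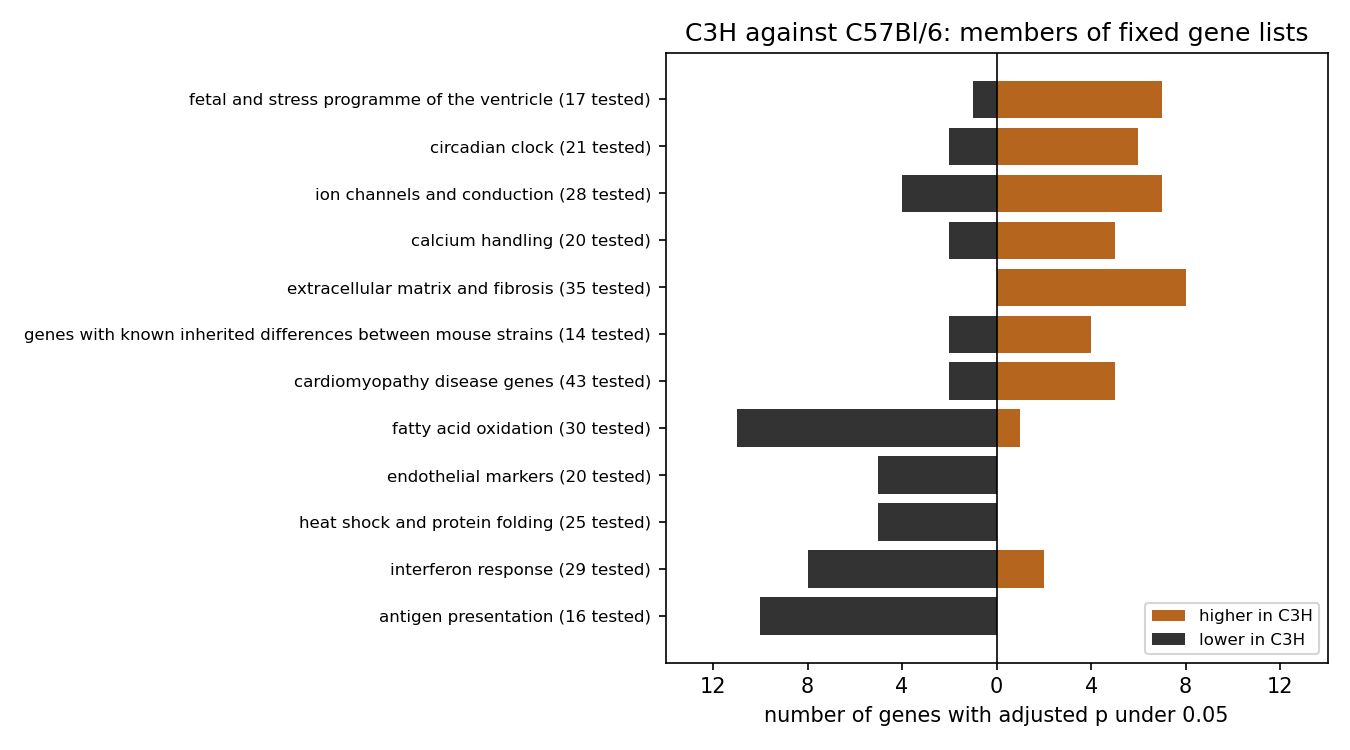
Bars give the number of genes of each fixed list that passed at an adjusted p under 0.05 and were higher (right) or lower (left) in C3H than in C57Bl/6, and the labels give the number tested. Antigen presentation had 10 lower and 0 higher members, and extracellular matrix and fibrosis 8 higher and 0 lower.

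The genes with the largest single differences included a potassium channel gene, a mitochondrial carrier gene and a heart muscle kinase gene. Among the 10 largest rises in C3H were Pdxdc1 (115-fold), the potassium channel gene Kcnj14 (43.9-fold), Gbp2b (4.46 on the log2 scale), Baiap2l1 (21.3-fold), Fmn1 (16.1-fold), Abhd1 (12.1-fold), the mitochondrial carrier gene Slc25a29 (11.6-fold), Ifi202b (10.6-fold), Ccnb1ip1 (8.23-fold) and Hddc3 (7.99-fold). The C57Bl/6 mean of Pdxdc1, Gbp2b, Ifi202b and Ccnb1ip1 lay below the dim filter, so that the sizes and ranks of their folds depend on the background. Over the alternatives the log2 difference ran from 3.07 to 5.99 for Gbp2b, 2.24 to 4.51 for Ifi202b and 1.74 to 4.62 for Ccnb1ip1. The 3 other probe sets of Pdxdc1 were all lower in C3H (by -4.48, -2.30 and -1.99), and with a pseudocount of 1 the probe set of highest mean was another one and the difference was -4.77. Among the 10 largest falls were Ang (38.2-fold), H2-K1, Efhd2 (24.2-fold), Nxpe4 (23.8-fold), H2-D1, Tnni3k, a heart muscle kinase (19.8-fold), 2210407C18Rik (16.3-fold), Gm26782 (-3.91 on the log2 scale), Tmem267 (11.1-fold) and Rpgrip1 (10.3-fold). The C3H mean of Ang, Nxpe4 and Gm26782 lay below the dim filter, with the same limit. Nxpe4 ran from -5.97 to -3.23 over the alternatives and Gm26782 from -4.52 to -2.94. With probe sets that can match several transcripts left out, other probe sets stood for Ang (-1.44 on the log2 scale, against -5.26) and Efhd2 (-0.83, against -4.59). The other tested probe set of Tnni3k was higher in C3H by 0.65 (adjusted p = 0.00151), so that the size and direction of its difference depend on the probe set.

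Of 14 tested genes known to differ by inheritance between mouse strains, 4 were higher in C3H and 2 lower, also over the list alone. They included Gbp2b, Wdfy1 (7.58-fold), Alad (3.81-fold) and Glo1 (2.47-fold), all higher in C3H. The lower members were Erdr1 (-0.48) and Trim30d (-1.90). The list's adjusted p was 0.021, 2.33e-06 with fry, and adjusted p = 0.119 with an estimated correlation. Nnt, part of which is deleted in C57BL/6J, differed by 0.01 (adjusted p = 0.953) in its brightest probe set, which checks nothing if it lies outside the deleted part, and was higher in C3H by 0.58 in a second set (adjusted p = 0.0263 over all probe sets). The 2 probe sets of H2-Ea, a class II gene silent in C57BL/6 mice, differed by -0.09 and 1.02 (adjusted p = 0.917 and 0.0681).

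The second question was where the cross lies. B6C3F1 hearts differed from C57Bl/6 in 502 genes, 270 higher and 232 lower. Centring each array on its median gave 213 higher and 102 lower. Myh7 was 2.45-fold higher than in C57Bl/6 (adjusted p = 0.000108), and the protease inhibitor gene Timp1 2.08-fold higher. Both belong to the fetal and stress list, of which 2 of 17 members were higher and 0 lower (6 and 0 over the list alone; adjusted p = 0.000774, 0.00451 with fry, and adjusted p = 0.1 with an estimated correlation). Of 35 matrix genes, 5 were higher and 0 lower (8 and 1 over the list alone), with Sparc (2.19-fold), Lum (1.72-fold), Tcf21 (1.44-fold) and Thbs4 (0.63 on the log2 scale) beside Timp1 (adjusted p = 5.95e-05, 0.101 with fry, and adjusted p = 0.556 with an estimated correlation). Timp1 did not pass without any one of B6C3F1 replicates 1 to 4 and C57Bl/6 replicates 1, 3 and 4 (adjusted p = 0.0513 to 0.111), nor Lum without C57Bl/6 replicate 3 (0.0503). Without the intensity trend neither Timp1 (0.0785) nor Lum (0.0554) passed. Of 16 antigen presentation genes, 6 were lower and 0 higher, also over the list alone. H2-K1 was 2.98-fold, H2-D1 2.38-fold, H2-Aa 2.28-fold and H2-Eb1 2.09-fold lower (adjusted p = 6.76e-05, 0.0489 with fry, and adjusted p = 0.369 with an estimated correlation). Of the 6 other probe sets of H2-D1, 3 were lower and 3 higher than in C57Bl/6. Of 7 nerve and Schwann cell markers only Gfra3 passed (1.87-fold higher; 4 adjusted over the list alone; adjusted p = 0.0462, 0.000513 with fry, and adjusted p = 0.176 with an estimated correlation). Gfra3 did not pass without any one of B6C3F1 replicates 1, 3 and 4 and C57Bl/6 replicates 1 and 5 (0.0656 to 0.0814). The nerve list did not pass without any one of B6C3F1 replicates 2 and 5, C3H replicates 1 and 5 and C57Bl/6 replicates 2 and 5 (0.0517 to 0.0778), and with no dim filter its adjusted p was 0.307. Of the 14 genes with inherited differences 4 were higher and 1 lower, also over the list alone. Wdfy1 was 3.75-fold, Alad 2.73-fold and Glo1 1.96-fold higher, Gbp2b was higher by 3.91 on the log2 scale and Erdr1 was lower by -0.55 (adjusted p = 0.0128, 6.85e-05 with fry, and adjusted p = 0.1 with an estimated correlation).

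The largest rises of B6C3F1 over C57Bl/6 were Pdxdc1 (53.7-fold), Kcnj14 (15.6-fold), Gbp2b, Fmn1 (11.3-fold) and Abhd1 (9.18-fold). The largest falls were 2610035D17Rik (5.52-fold), H2-K1, Smim10l1 (2.51-fold), H2-D1 and Nrn1 (2.35-fold). The lower mean of Pdxdc1, Gbp2b and 2610035D17Rik lay below the dim filter, so that the sizes of these 3 folds depend on the background. With a pseudocount of 1 another probe set stood for Pdxdc1, and it differed by -0.86 (adjusted p = 0.0533). Myh6 differed by -0.11 (adjusted p = 0.659), Nppa by 0.53 (adjusted p = 0.334), Nppb by 0.49 (adjusted p = 0.555), Nnt by -0.01 (adjusted p = 0.967) and H2-Ea by -0.22 (adjusted p = 0.804). The count depended on single arrays: it was 826 without C57Bl/6 replicate 2, 811 without B6C3F1 replicate 5 and 264 to 315 without any one of C57Bl/6 replicates 1, 3 and 4 and B6C3F1 replicates 1 to 4. Exchanging the labels of C57Bl/6 replicate 2 and B6C3F1 replicate 5 gave 809 genes, more than the true labels, with 159 of them among the 502. Under the exchanged labels, looked at after that count was seen, the antigen presentation and fetal lists passed in the same directions (adjusted p = 0.0363 and 0.0452). The matrix (0.0913), nerve (0.254) and inherited difference lists (0.476) did not pass, and oxidative phosphorylation did (0.0363; 4 of 43 higher and 1 lower). With an estimated correlation none of these 3 passed (adjusted p = 0.854 for antigen presentation and the fetal list, 0.901 for oxidative phosphorylation).

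Against C3H, B6C3F1 hearts differed in 813 genes, 470 higher and 343 lower, and in 405 with the poly-A control signal as a covariate. Centring each array on its median gave 266 higher and 408 lower. Of 21 clock genes, 9 were lower in B6C3F1 and 2 higher (10 and 3 over the list alone). Dbp was 4.84-fold, Wee1 2.16-fold, Tspan4 1.97-fold and Hlf 1.78-fold lower. Arntl, the partner of Clock in driving daily transcription, was 2.89-fold higher, and its relative Npas2 was higher by 1.15 on the log2 scale. The clock list's adjusted p was 0.00021, 0.025 with fry, and adjusted p = 0.289 with an estimated correlation. Of 16 antigen presentation genes 7 were higher and 0 lower (9 and 0 over the list alone), with H2-K1 11.6-fold, H2-D1 9.33-fold, H2-Aa 2.62-fold and H2-Eb1 2.02-fold higher (adjusted p = 3.12e-07, 0.00364 with fry, and adjusted p = 0.289 with an estimated correlation). Without probe sets that can match several transcripts H2-D1 differed by 0.69 and did not pass (0.0797). Of 30 fatty acid oxidation genes 5 were higher and 0 lower (8 and 2 over the list alone): Pdk4 (2.90-fold), Angptl4, an inhibitor of lipoprotein lipase (2.46-fold), Acot1 (1.84-fold), Cpt2 (1.36-fold) and Ucp3 (0.76 on the log2 scale). Its adjusted p was 0.024, 0.0635 with fry, and adjusted p = 0.59 with an estimated correlation. With the poly-A control signal as a covariate Acot1 (0.0876) and Cpt2 (0.082) did not pass. With the Gapdh ratio as a covariate the fatty acid list (0.204), Cpt2 (0.0572) and Hspa8 (0.151) did not pass. Of 25 heat shock genes only Hspa8 passed (1.25-fold higher; 5 adjusted over the list alone; adjusted p = 0.0249, 0.3 with fry, and adjusted p = 0.755 with an estimated correlation). After centring each array on its median the fatty acid and heat shock lists did not pass (0.0793 and 0.0754), nor did Hspa8 (0.119) and Cpt2 (0.0729). Hspa8 did not pass without any one of B6C3F1 replicates 2 to 5 and C3H replicates 1 to 3 (0.0649 to 0.0923). Without probe sets that can match several transcripts it differed by 0.11 (adjusted p = 0.788). The fatty acid list did not pass without any one of B6C3F1 replicate 2 and C3H replicates 2 and 3 (0.0516 to 0.113), nor the heat shock list without any one of B6C3F1 replicates 4 and 5 and C3H replicate 3 (0.104 to 0.212). The number of lists that passed was 8 without C3H replicate 5 and 2 without C3H replicate 3, against 4 with all arrays.

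Myh7 was 2.25-fold lower in B6C3F1 than in C3H, and Myl4 (1.71-fold) and Fhl1 (1.39-fold) were lower too. In the fetal and stress list 3 of 17 were lower and 0 higher (3 and 1 over the list alone; camera adjusted p = 0.157). The list passed with the poly-A control signal as a covariate (0.0235), while its adjusted p with an estimated correlation was 0.59. Of 20 endothelial markers 4 were higher in B6C3F1 and 0 lower (also over the list alone; camera adjusted p = 0.179, 0.0391 with the Gapdh ratio as a covariate, and adjusted p = 0.597 with an estimated correlation): Aplnr (3.14-fold), Rgcc (3.10-fold), Cdh5 (1.62-fold) and Cldn5 (1.49-fold). Cldn5 did not pass after centring each array on its median (adjusted p = 0.119), nor without any one of B6C3F1 replicates 2, 3 and 5, C3H replicates 2, 3 and 4 and C57Bl/6 replicate 3 (0.0504 to 0.102), and with the poly-A control signal as a covariate neither Cdh5 nor Fhl1 passed (0.0813 for both). The largest rises over C3H were Ang (18.1-fold), Efhd2 (3.58 on the log2 scale), H2-K1, Nxpe4 (11.5-fold) and Gm26782 (9.66-fold). With probe sets that can match several transcripts left out, Efhd2 rested on another probe set and differed by 0.23 (adjusted p = 0.594), and Ang by 1.37 (adjusted p = 0.0287). The C3H mean of Ang, Nxpe4 and Gm26782 lay below the dim filter. The largest falls were Lrrc10b (5.61-fold), Dbp, Fam122b (4.12-fold), Rtl3 (3.54-fold) and the thyroxine carrier gene Ttr (3.37-fold), which did not pass without probe sets that can match several transcripts (-1.35, adjusted p = 0.0909). Nppa differed by -0.29 (adjusted p = 0.657), Nppb by 1.13 (adjusted p = 0.133, and 0.0216 without C3H replicate 5), Myh6 by 0.15 (adjusted p = 0.546), Nnt by -0.03 (adjusted p = 0.928) and H2-Ea by -0.13 (adjusted p = 0.907).

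Over the 2052 genes that differed between the parents, the B6C3F1 arrays lay at a position of 0.457 ± 0.025 (SD, n = 5) between the C57Bl/6 mean at 0 and the C3H mean at 1. The 5 arrays ranged from 0.421 to 0.480, all below 0.5. The exact two-sided sign-flip permutation p against 0.5 was 0.0625, the smallest that 5 arrays can give, so that this test could not pass 0.05. The position was 0.507 without C57Bl/6 replicate 2 and B6C3F1 replicate 5, an alternative added after the data were seen. The B6C3F1 mean lay between the parental means for 1804 of the 2052 genes (87.9%). It was nearer to C57Bl/6 for 1103 genes and nearer to C3H for 949.

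**Figure D3:**
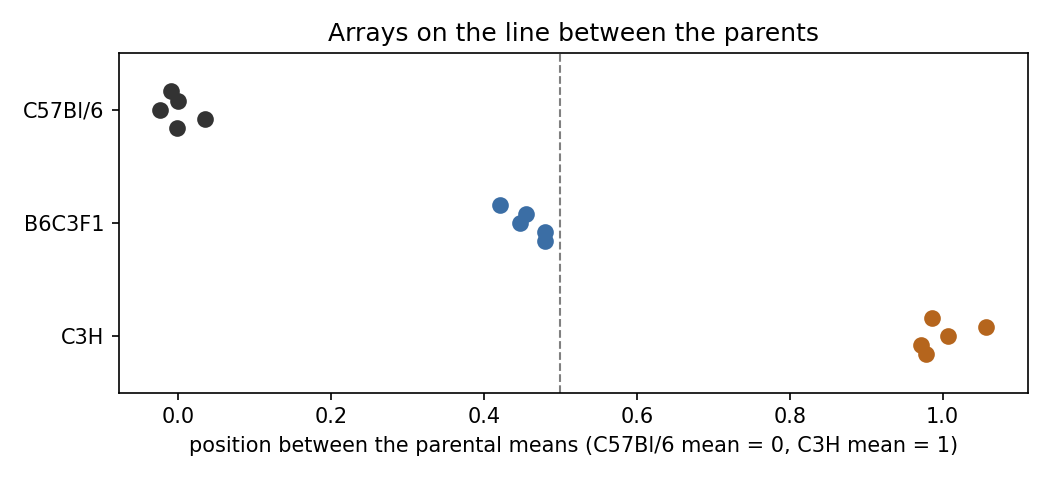
Each point is 1 array, placed on the line from the C57Bl/6 mean (0) to the C3H mean (1) over the 2052 genes that differed between the parents, and the dashed line marks 0.5. The B6C3F1 arrays lay at 0.421 to 0.480, while the parental arrays lie near 0 and 1 by construction, since they define the line.

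Against the midparent, 83 genes passed, 63 above and 20 below, and 50 passed with the poly-A control signal as a covariate. The largest differences above it were Pdxdc1 (5.00-fold), Gbp2b (3.21-fold), Ang (2.92-fold), Fmn1 (2.81-fold) and Hsd17b7, a gene of cholesterol synthesis (2.76-fold). The mean of one parent lay below the dim filter for Pdxdc1, Gbp2b and Ang, so that the sizes of these folds depend on the background. Gbp2b ranged from 1.03 to 2.43 on the log2 scale over the alternatives. Without probe sets that can match several transcripts Ang differed by 0.65 and did not pass (adjusted p = 0.352). The largest below it were the nuclear noncoding RNA Neat1 (2.42-fold), Fam122b (1.87-fold), Nme7 (1.87-fold), Ifrd2 (1.82-fold) and Dand5 (1.76-fold). The number was 210 without C3H replicate 5 and 41 to 52 without any one of B6C3F1 replicates 1 to 4. Dand5 (adjusted p = 0.0486) did not pass without any one of B6C3F1 replicates 1 to 4, C3H replicates 1 and 4 and C57Bl/6 replicates 1 to 5 (0.0512 to 0.166). Of B6C3F1 replicates, Nme7 depended on 2 and 3 (0.0501 and 0.0863 without them), Ifrd2 on 1, 2 and 4 (0.0544 to 0.0603) and Fam122b on 3 and 4 (0.0631 and 0.0552). With the midparent taken as the mean of the linear signals, an alternative added after the data were seen, 27 genes passed, 10 above and 17 below. Of the genes that passed against the linear midparent, Chm and Fam122b are X-linked and Eif2s3y is Y-linked. Males carry a single X and a single Y chromosome, so that neither midparent is the value inheritance would give for such genes. On the linear scale Hsd17b7 stayed above by 0.81 (adjusted p = 0.0124) and Neat1 below by -1.27 (adjusted p = 0.004), while Pdxdc1, Gbp2b, Ang and Fmn1 did not pass.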

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

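The tests of probe sequence and of mislabelled arrays were chosen after the results they concern were seen. In 321 groups of 5 arrays the gap between the highest or lowest array and its neighbour was set against the range of the group. In 23 of them (7.17%) it exceeded the critical value of 0.71, which chance exceeds in about 1 group in 20. B6C3F1 replicate 5 had 4 such values, and C3H replicates 4 and 5 and C57Bl/6 replicate 5 had 3 each.

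Poly-A control RNAs were brightest on C3H replicate 4 (12.48, the other C3H arrays 10.63 to 10.81; gap over range 0.903) and dimmest on C57Bl/6 replicate 5 (9.25, the others 10.45 to 10.55; 0.928). C3H replicate 4 also had the highest Gapdh 3 prime over 5 prime ratio of its strain (1.06; gap over range 0.740) and the highest signal of Slc25a29 (0.740). C3H replicate 5 was lowest of its strain in the mean of the clock list (0.755), Gm26782 (0.775) and Hk1 (0.721). C3H replicate 3 was highest in Smim10l1 (0.762). B6C3F1 replicate 5 was highest in Efhd2 (0.738), Cldn5 (0.803) and Hspd1 (0.737) and lowest in Alad (0.784). B6C3F1 replicate 1 was highest in Slc8a1 (0.750) and lowest in Hspa8 (0.768), and B6C3F1 replicate 3 was highest in the antiviral gene Rsad2 (0.859). Among the C57Bl/6 arrays, replicate 1 was highest in Gbp2b (0.735) and Fhl1 (0.788), and replicate 4 in Itpr2 (0.743). C57Bl/6 replicate 2 was lowest in Ifrd2 (0.796) and Cdh5 (0.857), and replicate 3 in Wee1 (0.724). C57Bl/6 replicate 5 was highest in Ccnb1ip1 (0.757) and lowest in Calr (0.891).

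Genes such as H2-K1 and Ang were so much lower in C3H than in C57Bl/6 that probe sequence may contribute, since probes that mismatch C3H RNA would give a lower C3H signal. Of the 2052 genes, 46.3% were higher in C3H, which argues against weaker binding of C3H RNA as the cause of the whole difference. This share cannot exclude probe sequence in general, since probe sets of Pdxdc1 and of H2-D1 went in both directions between the strains. For genes that did not pass, 57.1% of the other probe sets shared the direction of the one used. For genes at least 2-fold lower in C3H, 76.2% of their 181 other probe sets were lower too, and 35.9% passed as lower. The exact 95% interval of 69.4 to 82.2 treats probe sets of one gene as independent. For genes at least 2-fold higher, 99 of 132 were higher too. A mismatch and a lower transcript level cannot be told apart for these genes, since other probe sets can lie over further sequence differences. Chance alone is an unlikely source of the count: only the real split of 100 gave as many genes (2052, the highest other 974, the median of the others 0). The split with 974 was the real grouping but for an exchange of C3H replicate 1 and C57Bl/6 replicate 2.

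Clock genes of C3H hearts differed from those of B6C3F1 in opposite directions by daily phase, which an earlier or later hour of collection may explain. Evening genes such as Dbp fell by 0.82 on average in B6C3F1 and morning genes such as Arntl rose by 0.83, a difference of -1.65 (exact permutation p = 0.00794, the smallest for 5 against 5). An index of evening less morning genes ran from 1.57 to 2.35 in C3H, from -0.28 to 0.60 in B6C3F1 and from -0.37 to 1.83 in C57Bl/6, and the other 2 exact permutation tests gave 1.17 for C3H minus C57Bl/6 (p = 0.0556) and -0.49 for B6C3F1 minus C57Bl/6 (p = 0.373). With the poly-A control signal as a covariate the list's mean difference was -0.36 (camera adjusted p = 0.00118), 92.2% of its size without it. The list's call without it was lost at an estimated correlation (adjusted p = 0.289). Each C3H array (10.63 or above) was brighter in that signal than each other array (10.55 or below). Within strains the signal varied mainly through C3H replicate 4 and C57Bl/6 replicate 5, so that the covariate cannot exclude RNA input. Since no B6C3F1 array lay in the C3H range of the clock index, hour and strain stay confounded for that pair. A strain difference stays open, untested, and the hour of collection is not given in the sources used here.

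Exchanging B6C3F1 replicate 5 and C57Bl/6 replicate 2 gave 809 genes against 502 with the real labels. Thus 2 of 100 splits, the real one included, gave at least as many. That share was under 0.05, but it cannot exclude a structure of the arrays as a source of part of the 502 calls. Mislabelled arrays were argued against: left out of the strain means, B6C3F1 replicate 5 lay at 0.419 between the parents and C57Bl/6 replicate 2 at 0.128. With the Gapdh ratio as a covariate the exchanged labels gave 688 genes, against 541 for the real ones. The ratio thus did not account for the whole count, but the ratio of a single gene cannot exclude RNA quality or labelling. The split points to a structure of the arrays, and under it Nfe2l1 had the smallest adjusted p (0.000826). A state that these arrays share, such as RNA quality, dissection or handling, may remain, and a biological cause was not tested.

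For B6C3F1 minus C3H only the real split of 100 gave as many genes (813, the highest other 2), so that chance alone is an unlikely source of that count. For the midparent contrast 4 of 100 splits, the real one included, gave at least the real 83 genes, with 210 in the highest other. The splits for this contrast moved arrays among all 3 strains, so that the difference between the parents entered the shuffled groups. That share thus cannot tell whether the 83 calls off the midparent arose by chance. The 3 splits above the real one regroup most arrays by strain, which points to a structure of the arrays by strain.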

How the results depend on the processing

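The tests with the poly-A control signal as a covariate, the linear midparent and the 2 pairs of arrays left out were chosen after seeing the data. Over the alternatives, the calls of named genes that had passed stayed past the threshold in the same direction in 3658 cases, lost it in 98 and turned in 2. Those of passing lists stayed in 442 cases and were lost in 68. Of calls that had not passed, 6 for genes and 20 for lists passed under an alternative, and 19 and 1 changed direction. Unless a reason is given, the cause was not tested.

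Genes past the threshold for B6C3F1 minus C57Bl/6 were 315 after centring each array on its median, 304 without the intensity trend and 1314 with array weights, against 502. Against the midparent they were 132 with every probe set, 52 without the trend and 254 with array weights, against 83. With every probe set, where more features are tested, C3H minus C57Bl/6 gave 3148. A minimum of 1.5-fold, stricter by construction, gave 1151, 274, 476 and 54 in the 4 contrasts. With the poly-A covariate the counts were 1363 (C3H minus C57Bl/6), 405 (B6C3F1 minus C3H) and 50 (midparent). The linear midparent gave 27. Without both B6C3F1 replicate 5 and C57Bl/6 replicate 2 there were 1284 genes (B6C3F1 minus C57Bl/6) and 364 (midparent), and the position was 0.507. Leaving out the 2 arrays of outlying poly-A signal moved no count by over 1.5 times.

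Lists past the threshold for B6C3F1 minus C3H were 2 after centring, 2 without _x_at and _s_at probe sets and 8 with the Gapdh covariate, against 4. For B6C3F1 minus C57Bl/6 there were 8 without those probe sets. With an estimated correlation camera called 0, 0 and 0 lists in the 3 strain contrasts.

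Pdxdc1 turned with a pseudocount of 1, to -4.77 (C3H minus C57Bl/6) and -0.86 (B6C3F1 minus C57Bl/6), because another probe set then had the highest mean. After centring, H2-Ea differed by 0.012 between the parents and Nnt by 0.022 between B6C3F1 and C57Bl/6. Myh6 differed by -0.043 (B6C3F1 minus C3H) with the Gapdh covariate, and the cardiomyopathy list's mean was 0.0046 with the poly-A covariate, where the direction of its test changed. These 4 had not passed before either.

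Leaving out 1 array at a time gave 1640 to 2272, 264 to 826, 555 to 1117 and 41 to 210 genes in the 4 contrasts, and a position of 0.424 to 0.489. Lists ranged from 2 to 8 for B6C3F1 minus C3H. H2-Ea ranged from -0.30 to 0.22 (C3H minus C57Bl/6), -0.43 to 0.095 (B6C3F1 minus C57Bl/6) and -0.39 to 0.094 (B6C3F1 minus C3H). Nnt ranged from -0.051 to 0.067, -0.077 to 0.042 and -0.0791 to 0.0156 in the same order.

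With the replicate number as a block the counts were 2042, 491, 864 and 117, and the position 0.455. Same-numbered arrays of 2 strains correlated above 0.1 in 2 of 15 pairs. The block brought the clock list past the threshold between the parents (0.0498) and took the nerve list out for B6C3F1 minus C57Bl/6 (0.0536). The number of arrays and the signal over background, low for Gbp2b and Ang in one parent, are among the limits here, beside the scaling and the structure of the arrays shown above.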

Other observations

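The test of genes above the linear midparent and the test of X-linked genes were chosen after the results they concern were seen. Beside the lists described above, 5 of 21 glucocorticoid response genes were lower in C3H than in C57Bl/6 and 0 higher (camera adjusted p = 0.111). Of 22 adrenergic and cholinergic signalling genes 4 were higher and 2 lower (0.624), of 31 oxidative stress defence genes 3 and 5 (0.829), and of 15 mineralisation genes 2 and 0 (0.3505). Of 7 nerve and Schwann cell markers, Gfra3 (0.88) and Mbp (0.88) were higher in C3H, with an adjusted p of 0.133 by camera, 0.00203 by fry and 0.398 with an estimated correlation.

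Hearts of the cross lay beyond both parents, and passed against each of them, for 19 genes, 9 above and 10 below, chosen after their values were seen. By the mean alone, they lay beyond C57Bl/6 for 144 and beyond C3H for 104 of the 2052 genes that differed between the parents. Neat1 was lower than in C57Bl/6 by -1.21 and than in C3H by -1.33, and Sdhc, a subunit of succinate dehydrogenase, by -0.46 and -0.48. Retnla was higher by 0.83 and 1.07 and Fndc1 by 0.79 and 0.54. Positions between C57Bl/6 (0) and C3H (1), over the members of a list that passed between the parents, were not compared by a test. They were -0.13 ± 0.29 (SD, n = 5) for the clock, 0.06 ± 0.07 for endothelial markers, 0.23 ± 0.14 for fatty acid oxidation, 0.50 ± 0.15 for the fetal programme, 0.55 ± 0.15 for matrix and 0.76 ± 0.04 for inherited differences.

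Signals of the 2 parental alleles that add on the linear scale may account for part of the B6C3F1 values above the log2 midparent, as for Pdxdc1 and Gbp2b. Over the 498 genes at least 2-fold apart, the B6C3F1 mean lay 0.21 above the log2 midparent and -0.038 from the linear one. Of the 63 genes above the log2 midparent, 15.9% also passed above the linear one, among them Hsd17b7. A lost call was not always a lost difference. Il17re stayed above the linear midparent by 1.05 (adjusted p = 0.0847) and Gpr153 by 0.52 (0.0657), while Pdxdc1 (-0.11) and Ang (-0.12) did not. For 27 of the 63 the B6C3F1 mean lay above both parental means, while signals that add would lie between them. That count rests on means alone, in genes chosen for lying above the log2 midparent. Only 9 genes of all tested lay above both parents and passed against each.

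Neighbouring genes may share inherited differences in stretches of the genome. Of the genes past the threshold between the parents, 19.3% had a next tested gene in GRCm38.p6 order that had passed too, against a mean of 15.7% and a maximum of 18.6% in 10000 shuffles (permutation p = 0.0001, the smallest they can give). With pairs of one gene family left out it was 19.0%. The longest run was 5 genes of chromosome 1: Esrrg, Kcnk2, Cenpf, Ptpn14 and Smyd2. Its length was not set against the shuffles, so that it is no sign of shared differences by itself.

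The X-linked gene Fam122b lay near C57Bl/6 in the cross and Rtl3 lay nearer to C57Bl/6 than to C3H, and a single X chromosome from the C57Bl/6 parent may be the reason. As a set, the X-linked genes that differed between the parents did not lie at the level of C57Bl/6. Over the 42 that differed between the parents, B6C3F1 lay at 0.390 ± 0.088 (SD, n = 5; 0.265 to 0.481), not near 0, against 0.458 ± 0.024 over 2001 autosomal genes, and 17 of the 42, such as Timp1 and Hccs, were nearer to C3H. The mean passed the bound set against the explanation by less than its SD, a condition added after the value was seen, so that the explanation stays open. Genes elsewhere can also act on X-linked genes, so that this mean cannot tell which parent gave the X chromosome. The 3 Y-linked genes that differed, Eif2s3y, Kdm5d and Uty, lay at 1.05 ± 0.14, at the level of C3H. A Y chromosome from the C3H parent, and so an X from C57Bl/6, would give this, though only 3 genes show it.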
